A study of Mus musculus with 6 samples.

How the data were processed

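Polyadenylated RNA from 6 sorted mouse samples was sequenced, 3 FITChigh and 3 FITCdim. Per the labels' protocols, libraries were made with a strand-specific mRNA kit and sequenced as paired reads of 75 bp on a NextSeq instrument. Per the submitters' processing notes, the authors used STAR 2.5, edgeR and the mouse build mm10. The role and settings of each tool, the counting program, the annotation and the use of strand are not given in the sources used here. Reads shared by close paralogs (Myh6 and Myh7, Actc1 and Acta1, Hspa1a and Hspa1b, class I histocompatibility genes, Mt1 and Mt2) may have been divided in a way that cannot be checked, and fold changes of such genes are uncertain in that respect.

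The authors deposited 1 signal value per gene and library, which is a read count adjusted to a common library size and is neither a raw count nor a CPM value. Column totals were 2333473 to 2443707 in FITChigh and 2030583 to 2112872 in FITCdim, so the adjustment did not make them equal. Each column was matched to its sample by the sample's title. The table has 23410 gene lines, of which 6 are garbled (broken or surplus values) and were left out, leaving 23404 genes. Values are not divided by gene length, so they compare libraries and not genes. A gene called abundant, or the most abundant of its list, is one with a high adjusted read count, which also depends on its transcript length. Mitochondrially encoded genes were not analysed here.

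The adjusted values repeat in fixed patterns within each group, from which the number of reads behind each value was recovered by inverting a negative binomial quantile adjustment with a common dispersion of 0.0203. In every library 100% of the values came out whole within a tolerance of 0.1. Recovered reads were used for depth, for the floor of 3 reads, for counting intervals and for 1 alternative test, and not for the results in the comparisons. They numbered 2543794, 1589825 and 2931045 in FITChigh replicates 1, 2 and 3 and 3345994, 1705626 and 1852505 in FITCdim replicates 1, 2 and 3. One read was worth 0.607 to 1.54 adjusted counts. Counting intervals are exact binomial intervals at 95% on the reads summed over a group. Intervals and floors cover counting error alone, since amplified reads without molecular identifiers are not independent molecules.

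Genes with a value of at least 1 in at least 3 of the 6 libraries were kept (12907 genes). They were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (limma-trend, empirical Bayes, no block, two-sided) for FITChigh minus FITCdim, with Benjamini-Hochberg adjustment and a threshold of 0.05. The p-values measure the spread between these libraries. Replicates are numbered in accession order. No pair of libraries of a group agreed within sampling noise (chi-square per degree of freedom 3.87 to 6.60), so none looked like a library deposited again. This does not show that the libraries are independent. They were counted as replicates because the series text calls them biological replicates.

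A rule that chooses the test by the unit of the values, the gene lists, the genes to name and the alternatives were fixed before the data were examined. The choice of limma-trend was made once the values had been recognised as adjusted read counts. There were 38 lists, 15 of cell type markers and the others of pathways. Lists with at least 3 tested members (33) were tested with camera at a preset inter-gene correlation of 0.01, and beside it with camera at an estimated correlation and with fry, each adjusted over the lists. For cell type lists the values were also summed per library and compared by an exact two-sided permutation test over 20 assignments, whose smallest p is 0.1. Lists overlap, so their results are not independent.

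Named genes are the 12 largest rises and 12 largest falls among genes past the test, above the median of tested genes by mean level, without overlap between the groups and with a gene symbol other than that of a predicted gene. Further, in each list the member with the highest mean and up to 3 members past the test with the largest change and a mean of at least 1 are named, and Myh6, Tnnt2, Actc1, Myl2, Myl7, Nppa, Nppb, Pecam1, Kdr, Col1a1, Pdgfra, Ptprc, Rgs5 and Fos always are. In text on the whole table the 5 genes with the highest mean in each group are named. Not every gene that this rule takes is reported here. Any other gene named was chosen after its values were seen. Positions are those of the gene in the GENCODE annotation of the same build.

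On simulated reads for the FITChigh and FITCdim comparison, with 200 genes changed and 13024 genes tested, limma-trend recovered 45.5% of those changed 2-fold and 88.9% of those changed 4-fold, and 2.2% of its calls were false. The list test called the raised list and 0 of 20 unchanged lists there. Simulated genes were drawn independently of each other, so this does not show how the list test behaves on correlated genes. The estimated correlation of the real lists reached 0.78. In this simulation 2-fold changes were often missed, and a gene that did not pass in the data may still differ. The simulation gave 136 calls against 2072 in the data, which makes its adjusted threshold stricter, so the recovered shares may not carry over.

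Alternatives were pseudocounts of 0.5, 0.1 and 5, looser and stricter filters, recomputed scaling (trimmed mean of M-values, median of ratios, one common total, quantiles), limma without the trend, robust or with array weights, a test against a 2-fold change, a threshold of 0.01, the number tag in the titles as a block, and leaving out each library. In the block, the FITChigh and FITCdim libraries whose titles carry no number tag were treated as if they shared a tag. Added after seeing the data were limma-voom on the recovered reads, and the common total and quantiles for the list tests.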

Results

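Messenger RNA was sequenced from cardiomyocyte preparations of C57BL/6J mice that had been sorted into 2 sub-populations by green autofluorescence (the FITC channel) and by forward scatter (FSC), a measure that grows with particle size. The first sub-population was bright in FITC and dim in FSC (FITChigh), the second dim in FITC and bright in FSC (FITCdim). There were 3 libraries of each. The series text calls the 3 libraries of a group biological replicates. The libraries held 1589825 to 2931045 recovered reads in FITChigh and 1705626 to 3345994 in FITCdim. Of 23404 genes, 8105 were listed at 0 in every library. Levels are given as adjusted read counts, the deposited values, whose totals still differed between the gates. They were 2333473 to 2443707 in FITChigh and 2030583 to 2112872 in FITCdim. Relative to FITCdim, levels in FITChigh are therefore higher in this unit than they would be with one common total. On the log2 scale the libraries of a group correlated at a Pearson r, across genes, of 0.964 to 0.972, and libraries of different groups at 0.912 to 0.938. The title of the series gives the purpose as an autofluorescence-based isolation of highly purified ventricular cardiomyocytes, and the comparison of both gates asks how their RNA differed.

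The genes with the highest adjusted read counts, which also depend on transcript length, were genes of working heart muscle in both gates. Myh6, the main myosin heavy chain of the adult mouse heart (chromosome 14, 54941921 to 54966927 in mm10), led both groups, with 159480 ± 13528 adjusted read counts in FITChigh and 96706 ± 23944 in FITCdim (SD, n = 3 each). It took 6.65% ± 0.61 of the summed adjusted read counts in FITChigh and 4.63% ± 1.07 in FITCdim (SD, n = 3 each). Mb, which encodes myoglobin, followed at 62562 ± 8127 and 41779 ± 5677 (SD, n = 3 each), then Atp2a2, the calcium pump of the sarcoplasmic reticulum, at 40089 ± 4493 and 34272 ± 3295 (SD, n = 3 each). Tnnt2 and Tpm1 completed the top 5 genes of FITChigh, and Tpm1 and Actc1 those of FITCdim. The difference in Myh6, a log2 fold change of 0.75 (SE 0.32), did not pass the test across all genes (adjusted p = 0.14). Neither did that in Tnnt2, cardiac troponin T, at 0.63 (SE 0.23, adjusted p = 0.08), or that in Actc1, cardiac actin, at 0.26 (SE 0.21, adjusted p = 0.47). Myh6 and Tnnt2 were called higher by robust limma (adjusted p = 0.0013 and 0.0051), by limma-voom on recovered reads, tried after seeing the data (8.1e-04 and 0.0034), and without FITCdim replicate 3 (0.035 and 0.045). Tnnt2 was also called with the stricter filter on low values (0.041). With the title tag as a block, both were called higher as well (0.0041 for Myh6 and 0.0018 for Tnnt2). Over all 22 alternatives the adjusted p ran from 8.1e-04 to 1 for Myh6 and from 0.0018 to 1 for Tnnt2.

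The gates differed mainly by genes that were lower in FITChigh. Of 12907 genes tested, 1748 were lower and 324 were higher in FITChigh, and the falls were the larger changes. The median log2 fold change was -2.02 among the lower genes and 0.56 among the higher ones. C3, the central complement component (chromosome 17, 57203970 to 57228136), fell the most among called genes above the median level whose values did not overlap between the gates, predicted genes left out. It stood at 22.7 ± 12.7 adjusted read counts in FITChigh against 368 ± 183 in FITCdim (SD, n = 3 each; log2 fold change -3.97, SE 0.39, adjusted p = 2.7e-06). Trim7 (chromosome 11, 48826140 to 48852209) rose the most among them. It stood at 111 ± 4.54 against 55.3 ± 11.9 (SD, n = 3 each; log2 fold change 1.02, SE 0.20, adjusted p = 0.0016). The 12 largest falls among these genes also held Entpd1, an ectonucleotidase of vessel walls and immune cells, at -3.50, and the elastin gene Eln at -3.39. Fbln2, an elastic-fibre glycoprotein, stood at -3.34 and Fat4, a protocadherin, at -3.29. Ifitm3, an interferon-induced membrane protein, stood at -3.27 and the plasma membrane calcium pump Atp2b4 at -3.22. Pkhd1l1 fell by 3.52 on the log2 scale and Myo1d, an unconventional myosin, by 3.27. The other 3 were Dkk3, Myl7 and Myl4, described with the atrial genes.

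The 12 largest rises under the same limits included Myh7b, Cox6a2, Cox17 and Neat1, while Mrps12 at 0.98 and Mt1 at 0.94, whose values overlapped between the gates, were called but are not among them. Myh7b, a slow-type myosin heavy chain (chromosome 2, 155611212 to 155634307), stood at 1240 ± 94.6 adjusted read counts in FITChigh against 661 ± 117 in FITCdim (SD, n = 3 each; log2 fold change 0.92, SE 0.15, adjusted p = 3.0e-04). Cox6a2, the heart and muscle form of a cytochrome c oxidase subunit, rose by 0.91 (SE 0.22, adjusted p = 0.0098) and Cox17, a copper chaperone of the same enzyme, by 0.84 (SE 0.18, adjusted p = 0.0041). The nuclear long noncoding RNA Neat1 rose from 2938 ± 434 to 5250 ± 915 (SD, n = 3 each; adjusted p = 0.0022). Tead3, a transcription factor of the Hippo pathway, rose by 0.84 and Rnf207, a ubiquitin ligase gene, by 0.79. The others were Echdc2 at 0.91, Mon1a at 0.90, Ttc30b at 0.83, Rap1gap at 0.80 and Sec31b at 0.80. In 2040 of the called genes, 98.5%, the 3 values of one gate did not overlap those of the other. That held for 31.6% of all genes tested and is expected by chance for 10%.

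Testing used limma-trend on log2(value + 1) with Benjamini-Hochberg adjustment at 0.05, and fold changes on that scale understate those of low genes. The count of higher genes varied with the library left out. It was 67 without FITChigh replicate 1, 185 without FITChigh replicate 2 and 148 without FITCdim replicate 1. It was 341 without FITChigh replicate 3, 324 without FITCdim replicate 2 and 285 without FITCdim replicate 3. Fewer libraries also leave less power, which was not told apart from an effect of the library left out. The count of lower genes was 1152 without FITCdim replicate 1. Higher genes made up 15.6% of the calls. With each library rescaled to one common total they made up 2.0% (44 higher and 2139 lower), and the median log2 fold change of all genes moved from -0.01 to -0.18. After quantile normalization they made up 27.8% (467 higher and 1213 lower), and that median moved to 0.13.

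Of 32 cardiomyocyte markers, all tested, 10 rose in FITChigh, 0 fell and 22 did not pass. Their median log2 fold change was 0.46, which is 1.37-fold. Camera at a preset correlation called the list higher (adjusted p = 2.2e-09), with an adjusted p = 0.14 with an estimated correlation and 0.79 after quantile normalization. Besides Cox6a2, the largest rise past the test was that of Ckmt2, the mitochondrial creatine kinase of muscle, at 8367 ± 1409 adjusted read counts against 5108 ± 615 (SD, n = 3 each; log2 fold change 0.70, SE 0.17, adjusted p = 0.0089). Tnni3, cardiac troponin I, stood at 20760 ± 4880 against 12960 ± 1986 (SD, n = 3 each; 0.66, SE 0.21, adjusted p = 0.042). Adjusted over the list alone, 18 were higher and 0 lower. The summed level of the list was 523900 ± 22340 in FITChigh and 363700 ± 29740 in FITCdim (SD, n = 3 each). The exact two-sided permutation test of this difference gave p = 0.1, the smallest that 3 against 3 libraries allow. Of 33 tested sarcomere and Z-disc genes, 5 rose, 0 fell and 28 did not pass (median log2 fold change 0.38). Adjusted over the list alone, 13 were higher and 0 lower. Besides Tnni3, those with the largest rises were Obsl1, a cytoskeletal linker, at 0.65 (adjusted p = 0.01) and the M-band gene Myom1 at 0.61 (adjusted p = 0.012).

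Part of the nuclear genes of mitochondrial energy metabolism rose in FITChigh. Of 76 tested genes of oxidative phosphorylation, 16 rose, 0 fell and 60 did not pass (median log2 fold change 0.41). The list was called higher by camera (adjusted p = 8.7e-12), but not with an estimated correlation (adjusted p = 0.38) or by fry (adjusted p = 0.15). Adjusted over the list alone, 26 were higher and 0 lower. Ndufs6, a subunit of complex I, stood at 1374 ± 279 against 807 ± 133 adjusted read counts (SD, n = 3 each; log2 fold change 0.76, SE 0.16, adjusted p = 0.0037). Cycs, cytochrome c, stood at 1434 ± 228 against 866 ± 90.8 (SD, n = 3 each; 0.72, SE 0.14, adjusted p = 0.0021). The most abundant member, Atp5b, the beta subunit of the ATP synthase, did not pass (0.37, SE 0.19, adjusted p = 0.21). Of 24 genes of the TCA cycle and pyruvate dehydrogenase, 9 rose, 0 fell and 15 did not pass (median 0.40; adjusted over the list alone 16 higher and 0 lower). They were led by Idh2 at 0.67 (adjusted p = 0.007), Sucla2 at 0.65 (adjusted p = 0.0029) and Pdhb at 0.63 (adjusted p = 0.0032). Of 29 genes of fatty acid oxidation, 12 rose, 0 fell and 17 did not pass (median 0.40; adjusted over the list alone 17 higher and 0 lower). Among the risers were the thioesterase Acot13 at 0.59 (adjusted p = 0.023), the fatty acid carrier Fabp3 at 0.59 (adjusted p = 0.033) and the dehydrogenase Acadl at 0.57 (adjusted p = 0.0096).

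Flavin-dependent enzymes, whose cofactor fluoresces green, moved in both directions. Of 38 tested, 7 rose, 3 fell and 28 did not pass (median 0.30; adjusted over the list alone 9 higher and 3 lower). The risers were Etfa, Etfdh, Acadl, Acadm, Acadvl, Dld and Aifm1, of which all but Aifm1 also stand on the lists of the TCA cycle or fatty acid oxidation. Xdh, xanthine dehydrogenase, fell, with a log2 fold change of -2.52 (adjusted p = 5.4e-07). So did Maoa, monoamine oxidase A (-2.28, adjusted p = 0.0049), and Cyb5r3, a flavin-containing NADH-dependent reductase (-0.64, adjusted p = 0.0075). Maoa had 6 recovered reads over FITChigh against 36 over FITCdim. Whether these falls belong to myocytes or to other cells was not tested. The most abundant member, Sdha, stood at 0.30 (adjusted p = 0.16). Of 20 tested genes of glycolysis, Ldhb (0.55, adjusted p = 0.023) and Pgam2 (0.49, adjusted p = 0.047) rose, 0 fell and 18 did not pass (median 0.29; adjusted over the list alone 6 higher and 0 lower). The abundant Aldoa stood at 0.33 (adjusted p = 0.23). Of 25 genes of calcium handling and ion channels, 3 rose, 2 fell and 20 did not pass (median 0.27; adjusted over the list alone 4 higher and 2 lower). Hrc, a calcium-binding protein of the sarcoplasmic reticulum, rose by 0.59 (adjusted p = 0.014), while Kcna5, a voltage-gated potassium channel, fell (-2.60, adjusted p = 4.6e-06), as did Sri, sorcin (-0.67, adjusted p = 0.021).

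Whole lists were compared with all other genes by camera at a preset inter-gene correlation of 0.01. Higher in FITChigh by this test were cardiomyocyte markers (adjusted p = 2.2e-09), sarcomere and Z-disc (4.9e-08), oxidative phosphorylation (8.7e-12), TCA cycle (4.9e-08) and fatty acid oxidation (1.6e-07). So were flavin-dependent enzymes (5.6e-04), glycolysis (7.9e-04) and calcium handling (0.0025). None of these calls held with an estimated correlation, where the adjusted p was 0.38 for oxidative phosphorylation, 0.15 for glycolysis and 0.14 for each of the other 6 lists. After quantile normalization, tried after seeing the data, only oxidative phosphorylation of these 8 kept its call, and the adjusted p of cardiomyocyte markers was 0.79. In fry, which asks whether a list's genes move one way on balance, oxidative phosphorylation alone of the 8 did not pass (adjusted p = 0.15).

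Atrial genes were far lower in FITChigh. Myl7, the atrial regulatory myosin light chain (chromosome 11, 5896637 to 5898782), stood at 35.2 ± 16.5 adjusted read counts there against 339 ± 151 in FITCdim (SD, n = 3 each; log2 fold change -3.23, SE 0.30, adjusted p = 1.6e-06). Its partner Myl4, the atrial essential light chain, had a log2 fold change of -3.22 (SE 0.32, adjusted p = 3.3e-06) and Dkk3 one of -3.28 (SE 0.38, adjusted p = 1.4e-05). Nppa, the atrial natriuretic peptide gene (chromosome 4, 148000722 to 148002079), stood at 237 ± 78.4 against 800 ± 303 (SD, n = 3 each; -1.74, SE 0.25, adjusted p = 1.3e-04). Myl2, the ventricular regulatory light chain, stood at 30650 ± 6022 against 21760 ± 3138 (SD, n = 3 each; 0.49, SE 0.22, adjusted p = 0.16). It was called by robust limma (adjusted p = 0.029), by limma-voom (0.022) and with the title tag as a block (0.0039). Its adjusted p ran from 0.0039 to 1 over all 22 alternatives. Of 10 tested atrial markers, 9 fell, 0 rose and 1 did not pass, both over all genes and adjusted over the list alone (median log2 fold change -2.85). The one that did not pass was Kcnj3, a potassium channel subunit, at -0.20. Of the 5 ventricular markers, Irx3, a transcription factor, rose (0.66, SE 0.21, adjusted p = 0.041) and 4 did not pass (median 0.39; adjusted over the list alone 1 higher). The summed ventricular level was 30950 ± 6010 against 21980 ± 3145 (SD, n = 3 each; exact two-sided permutation p = 0.2), and the summed atrial level 439 ± 131 against 1956 ± 737.4 (SD, n = 3 each; exact two-sided permutation p = 0.1). Whether the difference between the gates differed between atrial and ventricular genes was not tested. The camera test called the atrial list lower (adjusted p = 2.4e-06) and the ventricular list higher (adjusted p = 0.011), and both had an adjusted p = 0.14 with an estimated correlation.

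**Figure D1:**
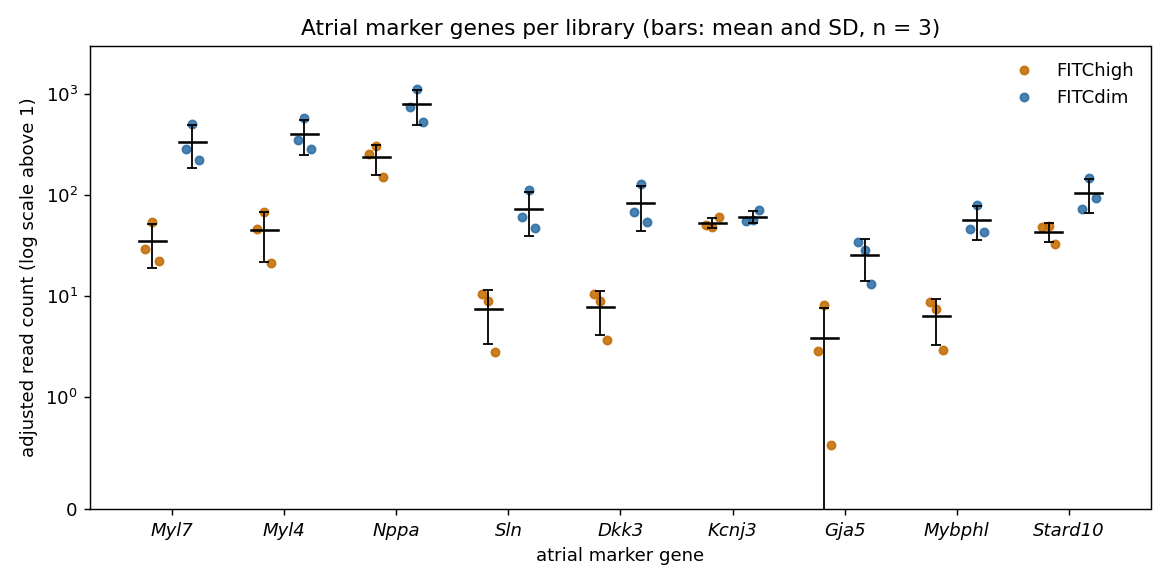
Adjusted read counts of 9 atrial marker genes per library on an axis that is logarithmic above 1 and linear below, with FITChigh in orange and FITCdim in blue, and the mean and SD of 3 libraries in black. Myl7 averaged 35.2 in FITChigh and 339 in FITCdim, while Kcnj3 had a log2 fold change of -0.20.

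The genes of the conduction system did not move as one. Cntn2, a contactin found in Purkinje fibres (chromosome 1, 132509427 to 132543256), stood at 7.59 ± 5.96 adjusted read counts in FITChigh against 73.3 ± 17.2 in FITCdim (SD, n = 3 each; log2 fold change -3.30, SE 0.39, adjusted p = 1.8e-05). Tbx3, a transcription factor of the conduction system, stood at 15.1 ± 0.953 against 42.4 ± 5.65 (SD, n = 3 each; -1.42, SE 0.26, adjusted p = 0.0011). The other 5 of 7 tested members did not pass, among them the most abundant, Cacna1g, a T-type calcium channel (0.12, adjusted p = 0.73), and Hcn4, the pacemaker channel (-0.08, SE 0.43, adjusted p = 0.93). Adjusted over the list alone, the count was also 2 lower and 0 higher. The list was not called by camera (adjusted p = 0.18; 0.33 with an estimated correlation), except without FITCdim replicate 1 (adjusted p = 0.029), and fry gave an adjusted p = 0.023.

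Markers of 6 kinds of cells other than myocytes were lower in FITChigh. Of the endothelial genes all 22 were lower, also adjusted over the list alone, with a median log2 fold change of -2.66, which is 6.33-fold. Pecam1, the endothelial adhesion molecule (chromosome 11, 106654217 to 106750628), stood at 94.2 ± 17.3 adjusted read counts in FITChigh against 624 ± 159 in FITCdim (SD, n = 3 each; -2.70, SE 0.18, adjusted p = 7.4e-08). Kdr, the main receptor for vascular endothelial growth factor, stood at 108 ± 40.9 against 634 ± 97.6 (SD, n = 3 each; -2.62, SE 0.23, adjusted p = 1.1e-06). The most abundant, Fabp4, a fatty acid carrier of capillaries, fell from 1225 ± 191 to 227 ± 62.0 (SD, n = 3 each). The largest falls were those of Cldn5, a tight junction gene, at -3.14, the phosphatase Ptprb at -3.06 and von Willebrand factor, Vwf, at -3.02. The summed endothelial level was 1273 ± 191 in FITChigh and 7767 ± 563 in FITCdim (SD, n = 3 each).

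Of the fibroblast genes, 16 of 17 tested markers were lower, 0 higher and 1 not past the test (median log2 fold change -2.63; the same counts adjusted over the list alone). Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042), stood at 4.56 ± 1.43 against 32.6 ± 4.11 adjusted read counts (SD, n = 3 each). Pdgfra, a receptor for platelet-derived growth factor, stood at 3.54 ± 1.502 against 16.7 ± 3.995 (SD, n = 3 each). Dcn, the proteoglycan decorin (chromosome 10, 97479609 to 97518143), stood at 25.8 ± 8.99 against 243 ± 94.3 (SD, n = 3 each). The most abundant member, Gsn, gelsolin, had a log2 fold change of -1.89 (adjusted p = 1.1e-05). Mfap5, a microfibril gene, had 2 recovered reads over FITChigh against 35 over FITCdim, a ratio of 15.5 with a 95% counting interval of 3.98 to 133.

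Of 13 mural markers, which label pericytes and smooth muscle, 11 fell, 0 rose and 2 did not pass (median -2.40; adjusted over the list alone 12 lower and 0 higher). Rgs5, a pericyte gene, stood at 32.8 ± 2.92 against 250 ± 56.7 adjusted read counts (SD, n = 3 each; -2.87, SE 0.19, adjusted p = 7.3e-08). The smooth muscle genes Tagln and Myh11 had log2 fold changes of -3.11 and -2.78. Abcc9, the most abundant member and a channel subunit also made by cardiomyocytes, did not pass (0.10, SE 0.18, adjusted p = 0.78). Of 16 tested macrophage and myeloid markers, 15 fell, 0 rose and 1 did not pass (median -2.40; the same adjusted over the list alone). Lyz2, lysozyme, stood at 34.7 ± 9.90 against 208 ± 111, and C1qc, a complement chain, at 5.66 ± 0.789 against 59.3 ± 30.1 (SD, n = 3 each). The mannose receptor gene Mrc1 stood at 7.61 ± 1.36 against 66.4 ± 27.5, and Ptprc, the gene of the leukocyte common antigen, at 2.02 ± 0.744 against 14.9 ± 6.04 (SD, n = 3 each). Itgam, an integrin chain of myeloid cells, had 2 recovered reads against 65, a ratio of 28.8 with a 95% counting interval of 7.66 to 243.

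Epicardial markers held the largest single falls of the cell type lists tested, with 8 of 9 tested members lower, 0 higher and 1 not past the test (median -2.63; the same adjusted over the list alone). Wt1, a transcription factor of the epicardium, stood at 3.32 ± 1.53 against 33.5 ± 10.3 adjusted read counts (SD, n = 3 each; -3.01, SE 0.39, adjusted p = 4.6e-05). Upk3b, a mesothelial uroplakin, stood at 2.06 ± 2.80 against 33.9 ± 6.65 (SD, n = 3 each; -3.91, SE 0.54, adjusted p = 8.8e-05). Msln, mesothelin (chromosome 17, 25748613 to 25754378), had 3 recovered reads against 121, a ratio of 35.7 with a 95% counting interval of 11.9 to 176. Lrrn4 had 2 against 56, a ratio of 24.8 with an interval of 6.56 to 210. Of 7 tested lymphatic and endocardial markers, 6 fell, 0 rose and 1, the transcription factor Prox1, did not pass (-0.26, adjusted p = 0.64). The counts were the same adjusted over the list alone, and the median was -2.25, also with Pdpn at its bound. Lyve1, a hyaluronan receptor of lymphatic vessels and resident macrophages, stood at 7.37 ± 5.43 against 58.7 ± 46.4, and Cytl1 at 1.99 ± 0.382 against 25.2 ± 18.1 (SD, n = 3 each). Pdpn, podoplanin, had 0 recovered reads in FITChigh and 26 in FITCdim and was at least 7.81-fold lower, against a floor of 3 reads over the group.

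Of 6 tested Schwann cell markers, Mbp, the myelin basic protein gene, fell, with 1 recovered read against 14 (ratio 12.4, 95% counting interval 1.89 to 525), and 5 did not pass, among them Erbb3 at -0.35. The median of the list was -0.38, 2 were lower adjusted over the list alone, and camera gave an adjusted p = 0.36 (0.47 with an estimated correlation). Of the erythroid and platelet markers only 2 could be tested, of which Pf4, a platelet chemokine, fell (-2.16, SE 0.57, adjusted p = 0.016) and Itga2b did not pass (0.15, adjusted p = 0.88). No neutrophil, lymphocyte or adipocyte marker passed the filter on low values. Csf3r and Cd4 each had 1 recovered read in FITChigh and 8 in FITCdim, and Plin1 had 2 and 0. Camera called the endothelial (adjusted p = 1.7e-20), fibroblast (5.6e-11), macrophage (9.4e-10), mural (1.6e-08), epicardial (8.8e-06) and lymphatic and endocardial (4.2e-05) lists lower. With an estimated correlation the adjusted p was 0.15 for the epicardial and 0.14 for each of the other 5 lists. Each of the exact permutation tests on the summed levels of these 6 lists gave p = 0.1, the smallest possible.

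**Figure D2:**
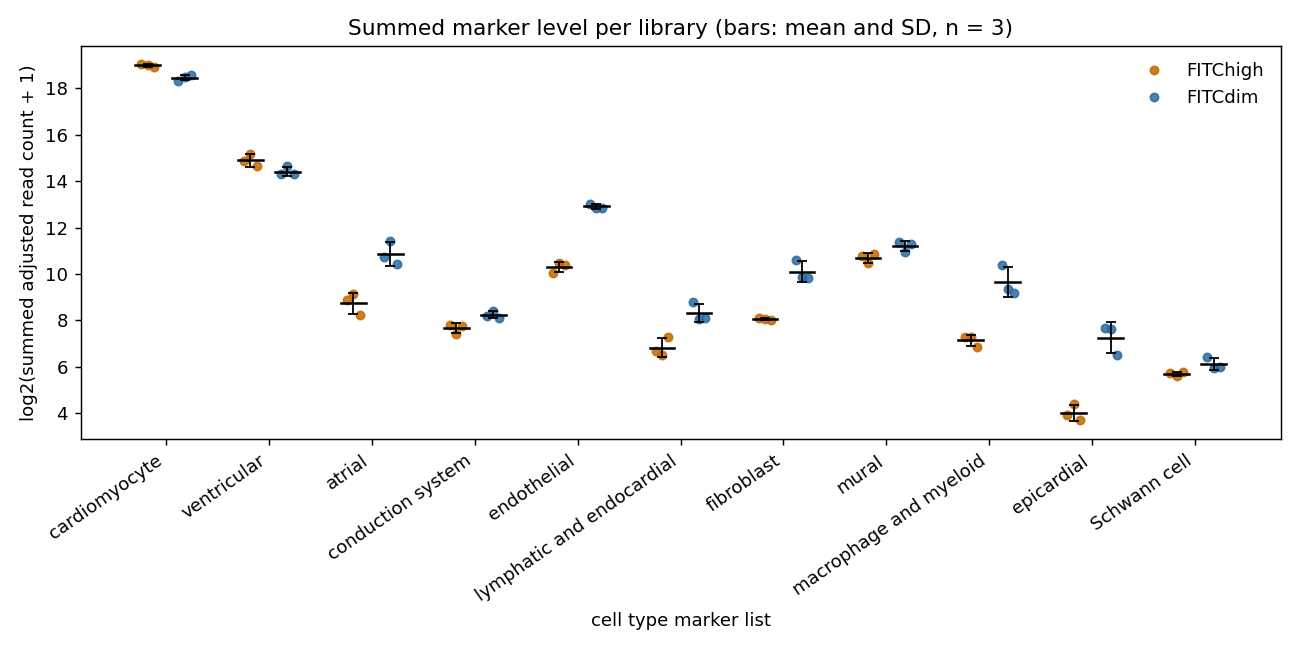
The log2 of the summed adjusted read count plus 1 of 11 cell type marker lists per library, with FITChigh in orange, FITCdim in blue, and the mean and SD of 3 libraries in black. The endothelial sum averaged 1273 in FITChigh and 7767 in FITCdim, while the cardiomyocyte sum averaged 523900 and 363700.

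Genes of the extracellular matrix, antigen presentation, the interferon response and cytokines were lower in FITChigh, the gate in which the endothelial sum was 6.14-fold lower. Of 33 matrix and basement membrane genes, 26 fell, 0 rose and 7 did not pass (median log2 fold change -2.01; adjusted over the list alone 28 lower and 1 higher). Fn1, fibronectin, stood at 29.5 ± 7.17 against 263 ± 97.8 adjusted read counts (SD, n = 3 each; -3.08, SE 0.24, adjusted p = 3.3e-07). Eln stood at 10.9 ± 3.51 against 127 ± 51.9 and Col5a2, a type V collagen chain, at 4.89 ± 5.18 against 39.7 ± 8.55 (SD, n = 3 each). The most abundant member, Hspg2, perlecan, fell by less, from 1855 ± 383 to 1083 ± 79.9 (SD, n = 3 each; -0.76, SE 0.15, adjusted p = 0.002). Of 15 genes of antigen presentation, 12 fell, 0 rose and 3 did not pass (median -1.86; the same adjusted over the list alone). B2m, the light chain of class I molecules, stood at 264 ± 57.8 against 944 ± 52.2, the invariant chain gene Cd74 at 33.5 ± 14.9 against 192 ± 95 and the class I gene H2-D1 at 18.9 ± 3.34 against 112 ± 30.1 (SD, n = 3 each). The immunoproteasome subunit Psmb8 had a log2 fold change of -2.60 (adjusted p = 0.0036).

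Of 22 tested interferon response genes, 17 fell, 0 rose and 5 did not pass (median -1.77; adjusted over the list alone 19 lower and 0 higher). Ifitm3 stood at 12.1 ± 2.37 against 131 ± 50.7 and Irf1, an interferon regulatory factor, at 7.52 ± 2.42 against 60.04 ± 2.92 (SD, n = 3 each). Ifi27l2a had 0 recovered reads against 28 and was at least 7.67-fold lower. Of 17 tested cytokine genes, 12 fell, 0 rose and 5 did not pass (median -2.05; adjusted over the list alone 14 lower and 0 higher). Cxcl12, a stromal chemokine, stood at 73.7 ± 28.8 against 439 ± 87.8 and Ccl2, a monocyte attractant, at 1.83 ± 1.44 against 19.97 ± 9.26 (SD, n = 3 each). Cxcl1 had 1 recovered read against 40, a ratio of 35.4 with a 95% counting interval of 6.01 to 1430. Camera called matrix (adjusted p = 3.0e-14), interferon (5.1e-12), cytokine (1.4e-07) and antigen presentation genes (6.3e-07) lower. With an estimated correlation the adjusted p was 0.15 for cytokines and 0.14 for each of the other 3 lists. Setting genes without a read in a gate to their bound left the medians of the matrix, interferon and cytokine lists at -2.01, -1.77 and -2.05.

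Part of the cell cycle genes fell in FITChigh. Of 24 tested, 7 fell, 0 rose and 17 did not pass (median -0.97; adjusted over the list alone 11 lower and 0 higher). Mki67, a marker of dividing cells, stood at 6.24 ± 3.06 against 37.8 ± 4.58 adjusted read counts and Top2a, a topoisomerase of dividing cells, at 1.22 ± 0.955 against 15.4 ± 3.01 (SD, n = 3 each). Ccna2, cyclin A, had 1 recovered read against 26, a ratio of 23.0 with a 95% counting interval of 3.79 to 945. The most abundant member, Cenpf, did not pass (-0.10, adjusted p = 0.86). Camera called the list lower (adjusted p = 4.6e-05; adjusted p = 0.14 with an estimated correlation). These genes were lower in the libraries in which endothelial, fibroblast and macrophage markers were lower.

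Immediate-early genes, which tissue dissociation induces, were lower in FITChigh for part of the list. Of 30 tested, 11 fell, 1 rose and 18 did not pass (median -0.33; adjusted over the list alone 12 lower and 1 higher). Camera gave an adjusted p = 0.018, and an adjusted p = 0.21 with an estimated correlation. The transcription factors Klf4 and Klf2, both also made by endothelium, stood at 52.1 ± 2.79 against 253 ± 30.7 and at 42.3 ± 8.89 against 167 ± 28.1 adjusted read counts (SD, n = 3 each). Egr3 (-2.69, adjusted p = 0.0052) and the abundant Egr1 (-0.41, adjusted p = 0.048) fell, and Gadd45g rose (0.68, adjusted p = 0.014). Fos did not pass, at 716 ± 144 against 874 ± 98.6 (SD, n = 3 each; -0.30, SE 0.16, adjusted p = 0.22). It was called lower with one common total (adjusted p = 0.026) and after quantile normalization (0.039), within a range of 0.026 to 1 over all 22 alternatives. Of 18 heat shock genes, the inducible Hsp70 genes Hspa1b (-1.29, adjusted p = 6.5e-04) and Hspa1a (-1, adjusted p = 0.004) fell and the co-chaperone Bag3 rose (0.54, adjusted p = 0.012). The other 15 did not pass, among them the abundant Hspb7 (0.28, adjusted p = 0.30). The counts were the same adjusted over the list alone, and the median was 0.24 (camera adjusted p = 0.084). Hspa1a and Hspa1b are near-identical copies, so how their reads were divided is uncertain.

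The remaining lists were not called by camera. In the hypertrophy and fetal program, Nppa, Myl4 and the actin cross-linker Actn1 (-0.90, adjusted p = 0.0076) fell, 0 rose and 15 of 18 tested genes did not pass (the same adjusted over the list alone). Its members outside the atrial list included Nppb, the B-type natriuretic peptide gene, at 572 ± 115 against 447 ± 92.5 (SD, n = 3 each; 0.36, SE 0.17, adjusted p = 0.20). Ankrd1, a stretch-responsive gene, stood at 3380 ± 274 against 2921 ± 249 (SD, n = 3 each; 0.21, adjusted p = 0.36). The list had a median of 0.15 and a mean of -0.27, and camera pointed up (adjusted p = 0.63) where fry pointed down (adjusted p = 0.60). Of 24 Wnt, Notch and cardiac transcription factor genes, 3 rose, 4 fell and 17 did not pass (median 0.16; adjusted over the list alone 4 higher and 4 lower). Hand2, a transcription factor of the heart, rose (0.69, adjusted p = 0.011). The Notch pathway genes Notch1 (-2.76, adjusted p = 2.7e-07), Jag1 (-2.52, adjusted p = 4.9e-04) and Hey1 (-2.06, adjusted p = 0.0014) fell, as did the abundant Ctnnb1, beta-catenin (-0.45, adjusted p = 0.022). Whether myocytes or other cells account for these falls was not tested. Camera gave an adjusted p = 0.25 (0.69 with an estimated correlation), or 0.044 without FITCdim replicate 3.

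Of 20 NRF2 target genes, Mt1, a metallothionein (0.94, adjusted p = 0.018), and Cat, catalase (0.47, adjusted p = 0.016), rose. Hmox1, heme oxygenase 1 (-1.25, adjusted p = 0.044), and Ftl1, ferritin light chain (-0.69, adjusted p = 0.015), fell. The abundant Fth1, ferritin heavy chain, did not pass (0.25, adjusted p = 0.33). The median was 0.13, 16 did not pass and the counts were the same adjusted over the list alone (camera adjusted p = 0.22). Of 19 tested hypoxia genes, Vegfa, the endothelial growth factor gene, rose (0.55, adjusted p = 0.0052). Ndrg1 (-2.41, adjusted p = 2.1e-06), Pfkfb3 (-1.98, adjusted p = 1.2e-04) and Lox (3 recovered reads against 21, ratio 6.20, 95% counting interval 1.85 to 32.5) fell, the last not by voom (adjusted p = 0.059; 0.022 to 0.84 over 21 alternatives). The other 15, among them Egln1 at 0.22, did not pass (median 0.01; adjusted over the list alone 4 higher and 4 lower; camera adjusted p = 0.79). Of 31 lysosomal genes, 4 fell, 0 rose and 27 did not pass (median -0.11; adjusted over the list alone 2 lower; camera adjusted p = 0.69). The immune cathepsin Ctss fell (-2.58, adjusted p = 0.0019), as did Ctsz (-1.77, adjusted p = 1.6e-04) and Gusb (-0.92, adjusted p = 0.042), while the abundant Ctsd stood at 0.23 (adjusted p = 0.35).

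Of 16 p53 target and apoptosis genes, 3 fell, 0 rose and 13 did not pass (median -0.21; the same adjusted over the list alone). They were the death receptor gene Tnfrsf10b (-2.53, adjusted p = 7.0e-04), Casp8 (-1.67, adjusted p = 0.0058) and Cdkn1a, a cell cycle inhibitor (-1.08, adjusted p = 0.0015), while the abundant Ccng1 stood at 0.18. Camera gave an adjusted p = 0.18 (adjusted p = 0.26 with an estimated correlation) and fry one of 0.0054. Of 23 genes of the unfolded protein and integrated stress response, 0 passed in limma-trend, over all genes or adjusted over the list alone, with 3 higher and 0 lower at unadjusted p < 0.05 and 1 higher and 0 lower by voom. Hspa5, the chaperone BiP, stood at 0.41 (adjusted p = 0.056; 0.039 by voom; 0.002 to 1 over 22 alternatives), and the median was 0.09 (camera adjusted p = 0.36). Of 76 cytosolic ribosomal protein genes, Rplp2 (0.68, adjusted p = 0.023) and the muscle form Rpl3l (0.64, adjusted p = 0.01) rose, and its ubiquitous paralog Rpl3 (-0.64, adjusted p = 0.038) and Rps23 (-0.52, adjusted p = 0.04) fell. The other 72 did not pass, 0 were called adjusted over the list alone, with 4 higher and 4 lower at unadjusted p < 0.05 and 2 higher and 3 lower by voom, and the median was 0. Camera gave this list an adjusted p = 0.32, but called it higher without FITChigh replicate 3 (0.0061) and without FITCdim replicate 2 (0.012). With an estimated correlation over all libraries it had an adjusted p = 0.86. Median and mean differed in sign for 3 more of the lists not called, that of Wnt, Notch and cardiac transcription factor genes (mean -0.14), that of hypoxia genes (mean -0.27) and that of the unfolded protein response (mean -0.06). For the first 2 of these and for the ribosomal proteins, camera pointed up and fry down. Mitochondrially encoded genes were not analysed here.

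**Figure D3:**
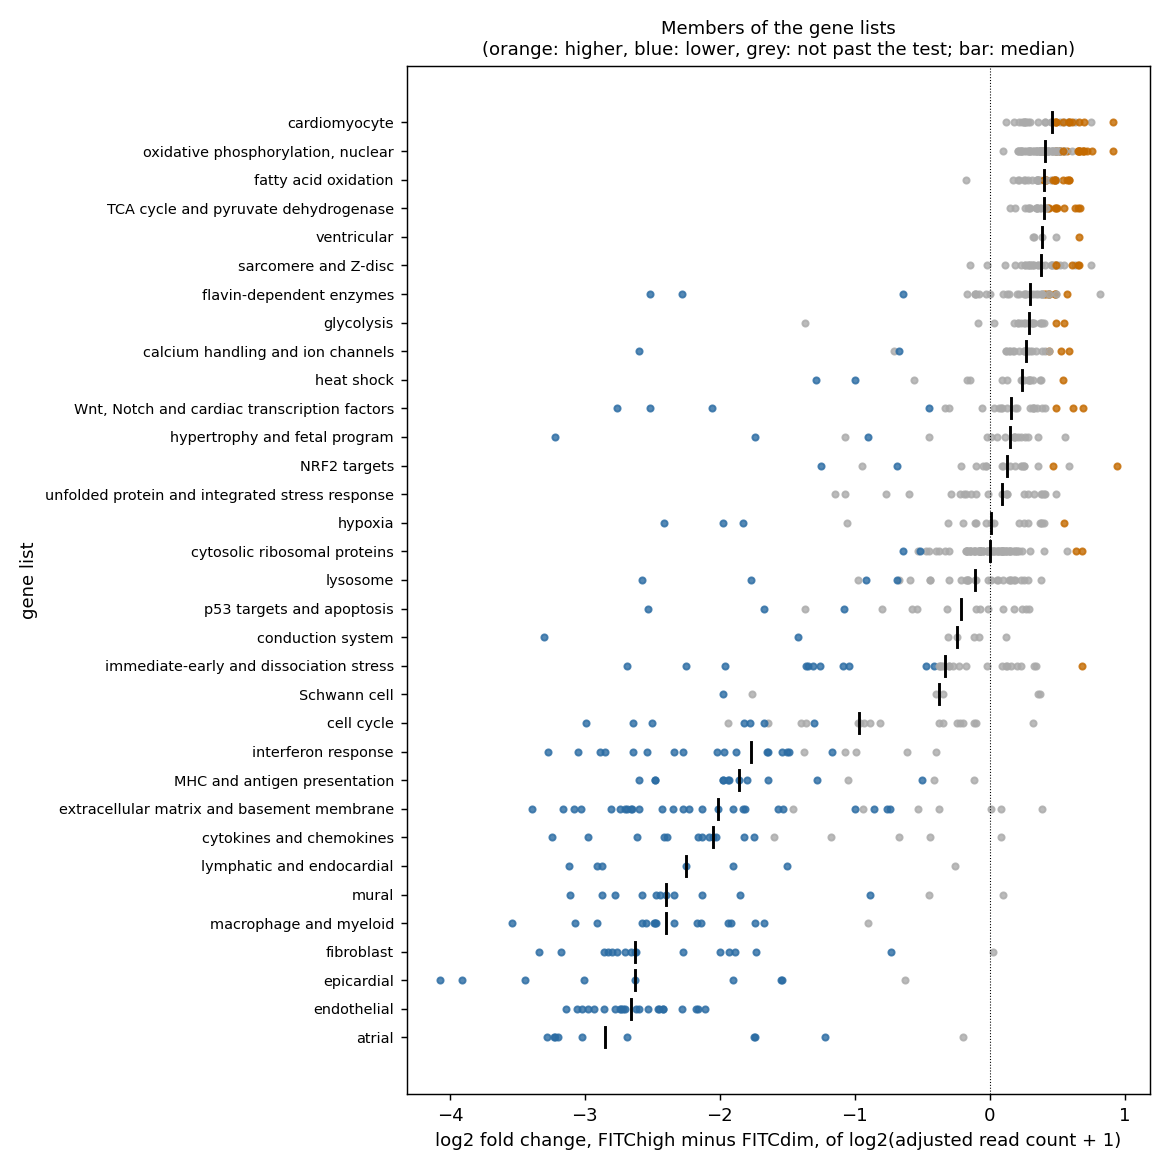
The log2 fold change, FITChigh minus FITCdim, of every tested member of the 33 gene lists with at least 3 tested members, sorted by the median of the list (black bar). Orange points were higher and blue points lower in FITChigh past the limma test, and the medians run from -2.85 for atrial markers to 0.46 for cardiomyocyte markers.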

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

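The alternatives were fixed before the data were examined, except limma-voom on the recovered reads and, for the list tests, the common total and quantiles, which were chosen after seeing the data. Against 324 genes higher and 1748 lower in FITChigh, 44 were higher with each library rescaled to one common total and 69 without the mean-variance trend. Tested by treat against a 2-fold change, 0 were higher and 561 lower, or 2 higher and 1122 lower at unadjusted p < 0.05, and limma-voom without that bound gave 360 higher and 1715 lower. At an adjusted p below 0.01, 54 were higher. The stricter tests lower the count by construction, and for the other settings the cause was not tested. Leaving out 1 library gave 67 to 341 higher genes and 1152 to 1672 lower ones, with 67 without FITChigh replicate 1, 185 without FITChigh replicate 2, and 148 higher and 1152 lower without FITCdim replicate 1. Of the 324 higher genes, 176 kept their call after quantile normalization and 41 without the trend, and of the 1748 lower genes, 1200 and 1447. The count models planned for raw counts were not run, since the deposited values are adjusted. The lists called by camera, 9 higher and 13 lower, became 0 and 0 with an estimated correlation, where 4 were higher and 7 lower at unadjusted p < 0.05 and the smallest adjusted p was 0.14, and 8 higher and 15 lower in fry. After quantile normalization 2 lists were higher and 13 lower. As the mean of the members' log2 values in place of the log2 of their sum, the difference in mural markers was -2.02 in place of -0.50 and that in epicardial markers -2.45 in place of -3.25. In the mural sum the abundant Abcc9, with a log2 fold change of 0.10, has the largest weight, and for epicardial markers the cause was not tested. Of 143 named genes tested, 118 were called, of which 61 lost the call under at least 1 alternative, all of them under treat among others, and 0 changed direction. On simulated reads, with fewer calls than in the data, limma-trend found 45.5% of 2-fold and 88.9% of 4-fold changes. Depth and number of libraries therefore limit what can be said of small changes.

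The titles of some libraries carry number tags shared between the gates, whose meaning the labels do not state. The titles of the other libraries, a FITChigh and a FITCdim library, carry no tag. The block treated these libraries as if they shared a tag. With the tag as a block, 1064 genes were higher and 2059 lower, against 324 and 1748 without it. Deviations from the group means, over 12907 genes, correlated at 0.071 between the libraries without a tag. Between libraries with the same tag they correlated at 0.125 and 0.175, and between all other libraries of different gates at -0.122 to -0.008. The libraries were not treated as pairs, since the labels state no pairing and the pair without a tag was below 0.1. That limit was not part of the planned design. Each library correlated best with the library of its own replicate number, which is a hint from the data and not from the design. The number of genes called depends on this choice. The block moved no count of called lists, and of 143 named genes 11 gained a call and 0 lost one. Those that gained one include Myh6 (adjusted p = 0.0041), Tnnt2 (0.0018), Myl2 (0.0039), Atp5b (0.01), Aldoa (0.013), Sdha (0.016) and Nppb (0.041).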

Other observations

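Genes outside the fixed lists were looked at after their values had been seen. Several genes known from the conduction system or from Purkinje fibres were lower in FITChigh beside Cntn2 and Tbx3. Etv1, a transcription factor of fast-conducting myocytes, stood at 6.82 ± 0.984 adjusted read counts against 20.3 ± 0.421 in FITCdim (SD, n = 3 each; limma log2 fold change -1.46, SE 0.33, adjusted p = 0.006). The sodium channel gene Scn10a (-2.22, adjusted p = 0.01), the calcium channel subunit gene Cacna2d2 (-1.92, adjusted p = 0.0013) and the guidance factor gene Slit2 (-1.42, adjusted p = 0.021) fell as well. The ion channel genes Kcne1 (-0.12, adjusted p = 0.81) and Kcnj5 (0, adjusted p = 0.99) and the transcription factor gene Tbx5 (-0.06, adjusted p = 0.86) did not pass. No test of these genes as a group was run.

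Of 9 gene families looked at in this way, those with called genes in 1 direction come first. Of 76 tested genes of mitochondrial ribosomal proteins, 11 rose and 0 fell, with a median log2 fold change of 0.38 (0.17 with a common total and 0.41 after quantile normalization). Mrps12, a protein of the small subunit, stood at 108 ± 24.8 adjusted read counts against 57.2 ± 28.4 (SD, n = 3 each; 0.98, SE 0.28, adjusted p = 0.023). Of 28 tested collagen chain genes, 19 fell and 0 rose, with a median of -1.99 (-1.43 after quantile normalization). Of 17 semaphorin genes, 7 fell and 0 rose (median -0.89; -0.44 after quantile normalization), and of 20 integrin genes, 8 fell and 0 rose (median -0.70; -0.33 after quantile normalization). Of 38 proteasome subunit genes 4 rose and 2 fell, of 40 mitochondrial solute carrier genes 2 rose and 3 fell, and of 14 voltage-gated potassium channel genes 1 rose and 1 fell. By limma-trend, 0 of 17 aminoacyl-tRNA synthetase genes (1 higher and 1 lower at unadjusted p < 0.05, 0 by voom) and 0 of 8 small nucleolar RNA host genes (0 at unadjusted p < 0.05, 0 by voom) were called. The nuclear long noncoding RNA Malat1 rose from 2446 ± 320 to 4094 ± 1373 (SD, n = 3 each; 0.70, SE 0.20, adjusted p = 0.021), as Neat1 did, while the imprinted noncoding RNA Meg3 fell (-1.58, SE 0.44, adjusted p = 0.021).

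The tests of the 3 patterns that follow were chosen after the result was seen, except the count of lists over other splits, the thinning of reads and the matching on length and level. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 2072 genes and the highest of the others 0, so that 1 of the 10 gave as many. For lists called by camera at the preset correlation, 1 of the 10 gave as many, with 22 for the real split and 18 for the highest of the others. Each of the other splits still sets 2 libraries of a gate against 1 and so holds part of the difference between the gates.

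Markers of endothelial, lymphatic and endocardial, fibroblast, mural, macrophage and epicardial cells were lower in FITChigh, with a median log2 fold change of -2.48 over 84 tested members. Scaling between libraries as the whole cause is argued against by a median of -2.22 under the scaling that brought it nearest to 0, and depth by a median of -2.51 after all libraries were thinned to 1589825 reads. A hypothesis that stays open is a smaller share of cells other than myocytes, or of their RNA, in FITChigh, which may lower the markers of all such cells alike. The 6 list medians spread over 0.41 (permutation test exchanging members between lists, p = 0.68), but the central 95% of 10000 resamples of the members reached a spread of 2.01, too wide to show that the cell types fell alike. Schwann cell markers, not among these lists, had a median of -0.38 over 6 tested genes, and the sort described in the labels used FITC and FSC.

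Atrial markers were lower in FITChigh, led in level by Nppa, Myl4 and Myl7. A fetal program of ventricular myocytes that raises the listed genes together in FITCdim is argued against by the 16 tested fetal program genes outside the atrial list. Their median was 0.18 (quartiles 0 and 0.24). A program limited to the atrial genes would not move these 16 and stays open. RNA of the 6 kinds of other cells stays open. The atrial sum of FITCdim replicate 2 over replicate 1 exceeded the highest ratio of those cells' sums 1.69-fold, but over replicate 3 it did not (0.94-fold). That last result came from the epicardial sum, at log2 7.61 in replicate 2 and 6.50 in replicate 3. There the atrial sum stood at 11.44 and 10.42, the endothelial at 12.86 and 12.86, and the fibroblast at 9.86 and 9.82. Macrophage (9.34 and 9.19), mural (10.97 and 11.28) and lymphatic and endocardial sums (8.08 and 8.12) also differed less. For these other types the contrast rests on replicate 2 alone, which is too little to decide. Atrial myocytes in the FITCdim gate, which selects by FITC and FSC and not by chamber, may be a source, and this stays open as a hypothesis. In 77.8% of the markers, 7 of 9, the highest of the FITCdim libraries was replicate 2, the exceptions being Kcnj3 and Gja5. The ventricular sum was also highest there, at log2 14.64 against 14.3 in replicate 1 and 14.3 in replicate 3. The cardiomyocyte sum was highest in replicate 3 (18.56) and the endothelial sum in replicate 1 (13.04). The share over all other genes was not computed, so this profile does not point to an atrial source.

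Cardiomyocyte and mitochondrial energy genes (170 genes of 5 lists) had a median log2 fold change of 0.41. Length or level stays open. Of 10000 random lists matched on both, 100% had a lower median (0.24, with 95% of them between 0.21 and 0.27). The matched genes were drawn independently of each other, while the members share spread between libraries. That range is therefore too narrow to decide. Scaling stays open, since the median less that of all genes was 0.04 after quantile normalization, against 0.39 to 0.42 under the other 3 scalings. More RNA of other cells in FITCdim, which may lower all myocyte genes alike, stays open as a hypothesis. The members scattered around a weighted mean of 0.40 with a chi-square per degree of freedom of 0.89 (range -0.18 to 0.91). This value cannot show that they moved alike. The standard errors it uses hold spread between libraries that the members share (estimated correlation 0.78 for oxidative phosphorylation), and such spread lowers it. No difference between the myocytes of both gates was tested apart from these, and one stays open.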
